A study of Homo sapiens with 12 samples.

How the data were processed

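Gene expression was measured by sequencing poly(A)-selected RNA from MDA-MB-231, a human triple-negative breast cancer cell line. Per the labels' protocols, the cells were transfected with a plasmid carrying Dicer, the ribonuclease that cuts microRNA precursors into mature microRNAs, and libraries were made with a NEBNext kit. The plasmid carried either wild-type Dicer or Dicer with 1 of 3 mutations, which the labels number and do not name. Each of the 4 groups held 3 libraries, 12 in total, and no cells without a plasmid or with an empty plasmid were analysed here. The wild-type libraries carry replicate numbers in the labels and the mutant libraries do not, so the numbers given to mutant libraries here are only names. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

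The authors deposited raw counts of read pairs per gene, with 64252 Ensembl gene IDs in each library. Per the file headers, these counts came from featureCounts 2.0.6 without regard to strand, over exons summed by gene ID, with a minimum mapping quality of 10 and the hg38 Ensembl gene track. The submitters' processing notes also name FastQC 0.11.8, cutadapt 1.9.1, STAR, SAMtools and DESeq2, and the versions of the last 3 were not given in the sources used here. Counting without strand means that reads from overlapping or antisense genes cannot be told apart. The mapping quality limit leaves out reads that fit several places, so levels of genes with near-identical copies are uncertain. Among the genes named here this concerns SPANXB1, KRT81, the histone genes and ribosomal protein genes, many of which have processed pseudogenes. Poly(A) selection misses most histone transcripts, which lack a poly(A) tail. Symbols were found for 56105 gene IDs (87.3%), which held 99.61% of all counts, and coordinates on hg38 came from GENCODE v29, which holds 56591 of the IDs. No column of per-sample values was left unused.

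Library totals ran from 13507341 to 17078273 counts. A gene at 0 in a whole group was given a floor of 3 counts per library when a lower bound on its fold was computed. For a gene with 1 to 3 counts in a group, the ratio is given with an exact (Clopper-Pearson) 95% interval. Such intervals and floors cover counting error only. Levels are CPM (counts scaled to library size) after trimmed mean of M-values (TMM) scaling, as mean ± SD of 3 libraries.

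The comparisons, the tests, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where the closing section says otherwise. Each mutation was compared with wild type and with each other mutation using edgeR 4.0.16 quasi-likelihood tests (R 4.3.3) with TMM scaling and robust estimation. All 12 libraries entered 1 fit with 8 residual degrees of freedom, without covariates. The filterByExpr function (minimum count 10, minimum total 15) kept 15094 genes, and 31029 genes had 0 counts in every library. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p for a gene comes from this test unless another is named. The standard error (SE) of a log2 fold change is approximate, the fold change divided by the square root of its F value. An F test over the 3 mutations asked which genes differed among the 4 groups.

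There were 24 gene lists: mesenchymal markers, epithelial markers, mesenchymal lineage genes, microRNA machinery, microRNA host transcripts, targets of let-7, of miR-200, of miR-21 and miR-17, and of miR-29 and miR-221, interferon-stimulated genes, NF-kB cytokines, G1/S and replication genes, G2/M genes, ATF4 and unfolded protein genes, cholesterol genes, hypoxia and glycolysis genes, YAP/TAZ targets, migration genes, luminal and basal breast markers, markers of other cell types, mitochondrial mRNAs, histone genes, ribosomal protein genes and nuclear-retained long RNAs. Each was tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, two-sided, and adjusted over the 24 lists within a comparison. Camera with an estimated correlation and fry were alternatives. Fry's p tests whether a list's genes move on balance one way and its mixed p whether they change in either direction, and neither compares the list with other genes.

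Named genes followed a fixed rule. DICER1 was named first. For each mutation against wild type, the 10 largest increases and 10 largest decreases were eligible among called genes with a mean of at least 5 CPM in the higher group, a symbol that is not a clone name, and libraries that did not overlap. For each pair of mutations 5 and 5 were taken, and of the genes called the same way in all 3 mutations, the 10 up and 10 down with the largest smallest change. Of each list, the rule took up to 4 members with the lowest adjusted p and called members against the direction of a list that passed. Members of the mesenchymal, epithelial and microRNA machinery lists could be named whatever their p.

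For microRNA sites, each 7-base seed match in the longest annotated 3' UTR was related across 12521 protein-coding genes (99.7% of those tested) to the log2 fold change. The model held UTR length, UTR GC content and mean expression. Genes needed at least 20 bases of UTR, and the median UTR was 1638 bases. The t value of each seed was ranked among 500 other 7-mers, and 15 seed families from the 5p strand were compared with 15 from the 3p strand by a two-sided permutation test with 100000 draws.

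Replicates were compared by Spearman correlation of log2 CPM across genes with a mean of at least 1 CPM, by the number of genes over 2-fold or 16-fold apart (at least 5 CPM in 1 of 2 libraries, offset 1 CPM), and by the chi-square of their counts over sampling noise for genes with at least 20 summed counts. No files held identical values. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for these steps and the figures.

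The edgeR test was checked on simulated counts for 15094 genes with known changes. For mutation 1 against wild type it recovered 90.9% of 66 genes changed 4-fold, 55.2% of 67 changed 2-fold and 23.9% of 67 changed 1.5-fold, with 4 false calls. Shares in that order were 97%, 64.2% and 22.4% for mutation 2 and 93.9%, 58.2% and 22.4% for mutation 3, with 3 false calls each. These counts were drawn with 1 spread per gene for all groups. In the data wild type varied more than the mutants (median dispersion, the spread beyond counting noise, 0.0935 against 0.0011). With each spread drawn separately and no change at all, a mean of 318, 327 and 321 genes were called for mutations 1, 2 and 3. False calls in the data may thus exceed those of the check. Camera found the planted list in simulated mutations 1, 2 and 3, and 0, 0 and 1 of 20 random lists had p under 0.05. Genes were drawn independently, so this does not check the preset correlation. A planted seed effect of 0.3 was estimated as 0.312 (SE 0.037) over 12521 genes.

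Alternatives were size factors by relative log expression (RLE), DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 5 CPM in 3 samples, DICER1 removed before scaling, each library left out in turn, only the 2 compared groups in the fit, a minimum of 2-fold, and 8-base sites for the seed test. After the data were seen, limma-voom with a variance for each group and a rule that called genes must not overlap between groups were added. The variance for each group is a weight shared by all genes.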

Results

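RNA from MDA-MB-231 breast cancer cells transfected with wild-type Dicer or with Dicer carrying mutation 1, 2 or 3 was sequenced in 12 libraries, 3 per group. The comparisons ask how gene expression with each mutant Dicer differed from that with the wild-type protein, and how the mutants differed from each other. The series title names microRNA reprogramming, mesenchymal cell fates and tumorigenic phenotypes as the subject. Library totals were 14136318, 17078273 and 14703721 counts for wild type and 15601196, 16219935 and 13761260 for mutation 1. They were 13507341, 14538605 and 16789948 counts for mutation 2 and 16455023, 15716954 and 13815164 for mutation 3.

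Wild-type replicate 1 and wild-type replicates 2 and 3 lay far apart. Replicate 1 carried 8.47 CPM of MUC5AC, a secreted gel-forming mucin, where wild-type replicates 2 and 3 carried 1010 and 1000, and 27.4 CPM of DICER1 where they carried 45.2 and 47.4. Mitochondrial mRNAs made up 1.34% of its counts, against 5.04% and 5.09% in wild-type replicates 2 and 3, 1.27 to 1.36% in mutation 1, 4.48 to 5.57% in mutation 2 and 4.81 to 5.05% in mutation 3. Its Spearman correlation across genes (which are not independent replicates) was 0.932 with each of wild-type replicates 2 and 3, which correlated at 0.998 with each other. Its value was 0.969 to 0.97 with the mutation 2 libraries, 0.936 to 0.937 with mutation 3 and 0.912 with mutation 1. Wild-type replicates 2 and 3 lay further from every mutant group, at 0.932 to 0.933 with mutation 2, 0.896 with mutation 3 and 0.852 to 0.853 with mutation 1. Over 16-fold from a mutant library lay 7 to 13 genes in wild-type replicate 1 and 48 to 108 in wild-type replicates 2 and 3. Between 1669 and 1672 genes lay over 2-fold apart between wild-type replicate 1 and the other wild-type libraries, and 45 to 47 lay over 16-fold apart, whereas at most 3 genes lay over 2-fold apart within any mutant group. The chi-square per degree of freedom over sampling noise was 148.21 and 141.37 for its pairs, 1.26 for wild-type replicates 2 and 3, and 1.3 to 3.51 within mutant groups. All libraries were kept under their labels, and some values without wild-type replicate 1 are given. Such values rest on wild-type replicates 2 and 3, which lay further from the mutants, and are not a cleaner estimate.

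**Figure D1:**
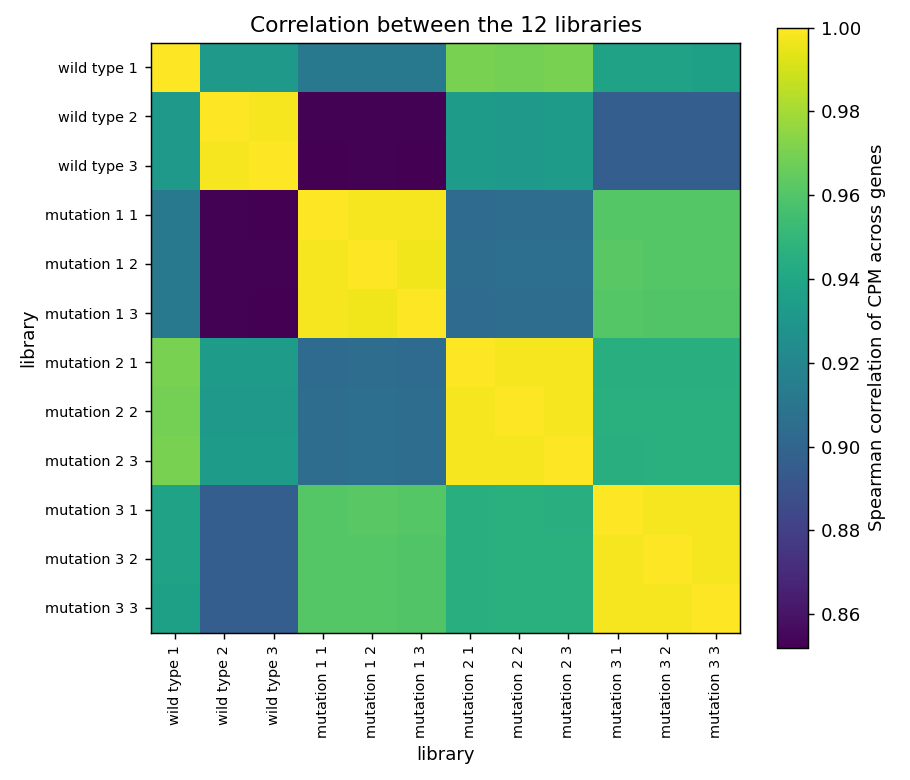
Spearman correlation of log2 CPM between each pair of the 12 libraries, with libraries on both axes and the correlation as colour. Wild-type replicate 1 correlates at 0.932 with wild-type replicates 2 and 3 and at up to 0.97 with the mutation 2 libraries.

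DICER1 (ENSG00000100697, chromosome 14, 95086228 to 95158010 on hg38) was expressed in every library. Its level was 40 ± 11 CPM in wild type (n = 3), 43.7 ± 1.52 with mutation 1, 45.3 ± 0.731 with mutation 2 and 39.4 ± 0.638 with mutation 3. The log2 fold changes against wild type were 0.13 (SE 0.16, adjusted p = 0.493), 0.18 (SE 0.16, adjusted p = 0.406) and -0.02 (SE 0.16, adjusted p = 0.916), so no difference passed the test. Without wild-type replicate 1 the values were -0.08 (adjusted p = 0.202), -0.02 (adjusted p = 0.723) and -0.23 (adjusted p = 0.000372), and DICER1 then fell with mutation 3. Counts of the gene do not separate plasmid from genomic transcripts, and with no cells lacking a plasmid the level does not check the transfection.

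Among the largest decreases with mutation 1 against wild type, MUC5AC (ENSG00000215182, chromosome 11, 1157953 to 1201138) lay at 0.0224 ± 0.0388 CPM against 675 ± 577 (n = 3 each). FGF13, ATP10A, SLCO1B3 and SCIN were at 0 in each mutation 1 library, at least 110-fold, 67.6-fold, 42.5-fold and 23-fold lower. FGF13, a growth factor homologue, had 0.0656 CPM in wild-type replicate 1 and a wild-type mean of 23.9 ± 20.7. ALDH3A1, an aldehyde dehydrogenase, lay at 0.0798 ± 0.138 against 55.1 ± 47.1 CPM, and KYNU, an enzyme of tryptophan breakdown, at 0.221 ± 0.212 against 46.1 ± 19.9. NALF1 lay at 0.0266 ± 0.0461 against 8.71 ± 5.06 and NAT1 at 0.0235 ± 0.0406 against 5.76 ± 1.09. AGR2 (ENSG00000106541, chromosome 7, 16791811 to 16833433), a disulfide isomerase, had 0.0458 ± 0.0397 CPM against 18.1 ± 6.2, a ratio of 382 (counting interval 105 to 3160). In the other direction, NFATC4 (ENSG00000100968, chromosome 14, 24365673 to 24379604), a calcium-regulated transcription factor, rose 79.8-fold from 0.27 ± 0.0504 to 22 ± 1.83 CPM. COLEC12, a scavenger receptor, rose 65.7-fold to 8.68 ± 1.16.

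The G1/S and DNA replication genes fell together with mutation 1. Of 37 measured members 35 fell, 0 rose and 2 did not pass, with a median log2 fold change of -1.16 (camera adjusted p = 1.24e-17). FEN1 (ENSG00000168496, chromosome 11, 61792637 to 61797244), the flap endonuclease of lagging-strand synthesis, fell from 208 ± 17.9 to 19.7 ± 2.08 CPM. PCNA (ENSG00000132646, chromosome 20, 5114953 to 5126626), the replication clamp, fell from 271 ± 10.4 to 63.9 ± 2.15. CDC6, which helps load the replicative helicase, fell from 122 ± 8.77 to 22.7 ± 1.12 CPM. Among G2/M genes 16 of 35 fell and 8 rose (median -0.20, adjusted p = 0.703), and 18 fell and 12 rose with a median of -0.07 without wild-type replicate 1.

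Interferon-stimulated genes were lower with mutation 1: 22 of 37 fell, 8 rose and 7 did not pass (median -0.68, adjusted p = 0.00518), and 9 rose and 22 fell adjusted over the list alone. The list had adjusted p = 0.0674 with an estimated correlation and 0.141 without wild-type replicate 1, with a median then of -0.63. IFIT3 (ENSG00000119917, chromosome 10, 89327894 to 89340971), an antiviral protein, fell from 94 ± 1.55 to 20.6 ± 1 CPM. IFIT2 fell from 49 ± 5.89 to 4.47 ± 0.416 and OASL (ENSG00000135114, chromosome 12, 121019111 to 121039242) from 30 ± 4.34 to 0.782 ± 0.195. Members that rose included STAT2, a signal transducer of interferon receptors (71.9 ± 23.2 to 142 ± 3.76 CPM), and BST2, a virus-tethering protein (148 ± 83.8 to 441 ± 7.39).

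Mesenchymal markers leaned upward with mutation 1: 16 of 27 rose, 5 fell and 6 did not pass (median 0.49, adjusted p = 0.0317). The list had adjusted p = 0.18 with an estimated correlation, 0.0511 without mutation 2 replicate 1 and 0.0584 without mutation 2 replicate 3, which share the spread estimate. TNC (ENSG00000041982, chromosome 9, 115019578 to 115118257), an extracellular matrix glycoprotein, rose from 65.1 ± 4.82 to 418 ± 12.7 CPM (log2 fold change 2.68, SE 0.06). FN1 (ENSG00000115414, chromosome 2, 215360440 to 215436172), which encodes fibronectin, rose from 408 ± 149 to 1260 ± 20.9. SNAI1, a repressor of CDH1, rose from 1.25 ± 1.09 to 19.5 ± 0.956 CPM (log2 fold change 3.98, and 4.94 without wild-type replicate 1). Not all members moved this way: CDH11, a mesenchymal cadherin, fell from 237 ± 14 to 193 ± 2.89. VIM, the intermediate filament vimentin, lay at 1520 ± 48.6 against 1580 ± 514 (adjusted p = 0.79, and past the threshold without wild-type replicate 1 with a log2 fold change of -0.30). Of the 30 epithelial markers 11 rose and 8 fell (median 0.41, adjusted p = 0.52, and 0.00524 without wild-type replicate 1, when 19 rose and 8 fell). CLDN7, a tight junction claudin, rose from 26.6 ± 3.93 to 50.2 ± 0.766 CPM, and KRT7, a keratin of simple epithelia, fell from 666 ± 57.9 to 444 ± 15.4. CDH1 (ENSG00000039068, chromosome 16, 68737225 to 68835548), the epithelial cadherin, lay at 11.1 ± 1.33 CPM against 5.42 ± 7.3 (adjusted p = 0.222), because wild-type replicate 1 held 13.8 CPM and wild-type replicates 2 and 3 held 1.17 and 1.23. Without wild-type replicate 1 its log2 fold change was 3.21 (adjusted p = 5.96e-32). Of the mesenchymal markers 17 rose and 8 fell without that library.

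The microRNA machinery moved in both directions with mutation 1, with 12 of 26 members higher and 9 lower (median 0.18, mean -0.05, adjusted p = 0.711). DGCR8 (ENSG00000128191, chromosome 22, 20080232 to 20111877), the partner of DROSHA in cutting primary microRNA transcripts, fell from 52.6 ± 14.7 to 4.19 ± 0.32 CPM (log2 fold change -3.65, SE 0.20, adjusted p = 6.41e-08). AGO2 (ENSG00000123908, chromosome 8, 140520156 to 140635619), the slicing Argonaute, rose from 16.1 ± 2.55 to 52.8 ± 1.91. TENT2, a terminal nucleotidyltransferase, rose from 27.3 ± 1.35 to 58.1 ± 0.489, and DDX5, an RNA helicase of the DROSHA complex, fell from 659 ± 145 to 199 ± 7.46 CPM. Of 18 microRNA host transcripts 4 rose and 9 fell (median -1.18, adjusted p = 0.318), with MIR3142HG at 0.319 ± 0.141 CPM against 15.8 ± 7.54. The 4 lists of microRNA targets did not pass. Targets of let-7 had 11 of 30 up and 13 down (median -0.19, adjusted p = 0.765) and those of miR-200 11 of 27 up and 7 down (0.06, 0.219). Targets of miR-21 and miR-17 had 15 of 32 up and 9 down (0.37, 0.0938), and miR-29 and miR-221 targets 20 of 35 up and 6 down (0.53, 0.061). The last had adjusted p = 0.00242 without wild-type replicate 1 and 0.0383 without wild-type replicate 2. Of miR-200 targets 13 rose and 12 fell without wild-type replicate 1 (median 0.11), and let-7 targets then had a median of -0.33.

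Hypoxia and glycolysis genes rose with mutation 1 in 20 of 32 members and fell in 2 (median 0.85, adjusted p = 0.00126, 21 up and 2 down adjusted over the list alone, and adjusted p = 0.598 with an estimated correlation). ADM (ENSG00000148926, chromosome 11, 10304680 to 10307397), which encodes a vasodilator peptide, rose from 45.1 ± 9.34 to 369 ± 5.45 CPM. VEGFA (ENSG00000112715, chromosome 6, 43770184 to 43786487), the vascular growth factor, rose from 169 ± 58.6 to 1040 ± 14.9, while ANGPTL4 fell from 12.5 ± 4.33 to 2.62 ± 0.497. The list sat at 0.18 in wild-type replicate 1 and at -1.17 and -1.16 in wild-type replicates 2 and 3 (mean log2 CPM around each gene's mean), and its median was 1.36 without wild-type replicate 1. Nuclear-retained long RNAs rose in 5 of 9 members and fell in 0 (median 1.05, adjusted p = 0.00311, and 0.362 with an estimated correlation). KCNQ1OT1, an imprinted antisense RNA, rose from 3.6 ± 1.79 to 67.7 ± 2.78 CPM and MALAT1, an RNA of nuclear speckles, from 724 ± 244 to 2400 ± 60.4. Ribosomal protein genes rose in 57 of 71 members and fell in 3 (median 0.38, adjusted p = 0.000515, 58 up and 3 down adjusted over the list alone, and adjusted p = 0.429 with an estimated correlation). RPL12 rose from 766 ± 30.3 to 1310 ± 47.7 CPM. Mitochondrial mRNAs fell in 10 of 13 members and rose in 0 (median -2.03, adjusted p = 0.00479, and 0.477 with an estimated correlation). MT-ND3 fell from 610 ± 24.2 to 49.1 ± 2.25 CPM. Their share of counts in wild-type replicate 1 was at the level of mutation 1. Counts up and down without that library were 1 and 12 for mitochondrial mRNAs, 64 and 5 for ribosomal protein genes and 6 and 1 for nuclear-retained RNAs.

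Migration genes rose with mutation 1 in 20 of 38 members and fell in 6 (median 0.43, adjusted p = 0.0317, and 0.362 with an estimated correlation). TIMP2, a metalloproteinase inhibitor, rose from 614 ± 28.1 to 1130 ± 18.5 CPM and RHOB, a small GTPase, from 54.1 ± 4.4 to 128 ± 3.95. SERPINE2, a protease inhibitor, was among those that fell. Other lists did not pass against wild type, and medians and adjusted p values follow in this order. ATF4 and unfolded protein genes had 15 of 31 up and 10 down (0.15, mean -0.06, adjusted p = 0.343) and cholesterol genes 9 of 25 up and 8 down (0.22, 0.378). YAP/TAZ targets had 11 of 22 up and 6 down (0.28, 0.343) and luminal and basal markers 5 of 14 up and 5 down (0.21, mean -1.25, adjusted p = 0.726). Markers of other cell types had 1 of 7 up and 3 down (-0.83, 0.298), and histone genes 4 of 12 up and 1 down (0.61, 0.212). Mesenchymal lineage genes had 7 of 16 up and 6 down (0.45, 0.259, 8 and 6 adjusted over the list alone). NF-kB cytokines had 13 of 29 up and 11 down (0.58, 0.406, 15 and 11 adjusted over the list alone), with adjusted p = 0.0205 without wild-type replicate 1. For lists with no count given after adjustment over the list alone, it equalled the count over all genes. The counts up and down were, without wild-type replicate 1, 23 and 12 for migration genes, 8 and 5 for luminal and basal markers (median 0.37) and 5 and 2 for histone genes. They were 14 and 8 for YAP/TAZ targets (median 0.57), 11 and 10 for cholesterol genes (median 0.06) and 16 and 13 for ATF4 and unfolded protein genes (median 0.23).

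In total 10412 of 15094 genes were called between mutation 1 and wild type (69%), 4902 higher and 5510 lower with the mutation, and 5302 were called and at least 2-fold apart. The libraries of the groups did not overlap for 10269 genes (68%), where chance gives 10%. Of the 34 genes that the rule named by size of change, 9 moved by over 1.5 times without wild-type replicate 1, and 0 lost their call. The rule had already required a call and no overlap with that library included, and it lay nearest the mutants. That no call was lost thus says little about how firm the calls are.

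Mutation 2 gave fewer calls against wild type than mutations 1 and 3 did. KRT81 (ENSG00000205426, chromosome 12, 52285913 to 52291534), a hair keratin, was 3520-fold lower at 0.301 ± 0.0664 CPM against 1070 ± 782, from 167 CPM in wild-type replicate 1 and 1540 and 1510 in the others. AGR2 was at 0 in each mutation 2 library and at least 94.5-fold lower, and SLAMF7, a lymphocyte surface receptor, at least 85.6-fold lower (16.4 ± 7.6 CPM in wild type). FOXA2 (ENSG00000125798, chromosome 20, 22581005 to 22585455), a transcription factor of endoderm, was 299-fold lower at 0.181 ± 0.157 against 58.9 ± 36.7 CPM. PAPPA, a protease that frees insulin-like growth factors, rose 19.5-fold from 0.963 ± 0.987 to 18.5 ± 0.985 CPM (log2 fold change 4.28, and 5.54 without wild-type replicate 1). TNS1, a focal adhesion protein, rose 11.5-fold from 3.69 ± 2.83 to 42 ± 1.71 (log2 fold change 3.52, and 4.35 without wild-type replicate 1). PTPRN2 (ENSG00000155093, chromosome 7, 157539056 to 158587788), a protein of secretory granules, rose 31.4-fold to 18.1 ± 1.99 CPM (log2 fold change 4.97, and 5.63 without wild-type replicate 2).

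The cell cycle lists did not pass with mutation 2. Of the 37 G1/S genes 14 rose and 4 fell (median 0.12, adjusted p = 0.113, 15 and 4 adjusted over the list alone). CLSPN, a replication checkpoint protein, rose from 56.7 ± 3.79 to 86.6 ± 3.81 CPM and MCM2, a helicase subunit, from 175 ± 9.45 to 220 ± 6.01. G2/M genes had 11 of 35 up and 8 down (median 0.09, adjusted p = 0.361, and a median of 0.24 with adjusted p = 0.0165 without wild-type replicate 1). Interferon-stimulated genes had 6 of 37 up and 5 down (median -0.12, adjusted p = 0.814), and 12 up and 15 down with a median of -0.07 without wild-type replicate 1. Ribosomal protein genes fell with mutation 2 in 49 of 71 members and rose in 1 (median -0.30, adjusted p = 1.51e-09, 1 up and 54 down adjusted over the list alone, and adjusted p = 0.302 with an estimated correlation). RPL13A fell from 1720 ± 51.6 to 1170 ± 26.5 CPM, and RPS12 was the member that rose. Cholesterol genes fell in 12 of 25 members and rose in 2 (median -0.28, adjusted p = 0.0281, 2 up and 13 down adjusted over the list alone, and adjusted p = 0.302 with an estimated correlation). IDI1, an isomerase of isoprenoid synthesis, fell from 53.4 ± 2.8 to 29.2 ± 1.44 CPM. Histone genes fell in 6 of 12 members and rose in 0 (median -0.51, adjusted p = 0.025, 0.214 with an estimated correlation and 0.176 without wild-type replicate 1). H2BC5 fell from 6.42 ± 0.932 to 2.18 ± 0.124 CPM. G1/S genes and G2/M genes each had 23 up and 9 down without wild-type replicate 1, ribosomal protein genes 10 and 54, cholesterol genes 4 and 14 and histone genes 2 and 6.

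The microRNA machinery rose with mutation 2 in 12 of 26 members and fell in 4 (median 0.19, adjusted p = 0.0494, 14 and 4 adjusted over the list alone, and adjusted p = 0.214 with an estimated correlation). TNRC6C, a scaffold of silencing complexes, rose from 13.6 ± 1.5 to 27.9 ± 2.59 CPM, DROSHA, the nuclear microRNA nuclease, from 75.4 ± 2.27 to 104 ± 0.859, and AGO2 to 27.8 ± 0.895. DGCR8 lay at 55.2 ± 2.87 against 52.6 ± 14.7 CPM (adjusted p = 0.776, and 0.0202 with a log2 fold change of -0.14 without wild-type replicate 1). The call of the list microRNA biogenesis and silencing machinery, mutation 2 vs wild type, ended when wild-type replicate 1 (0.586), any mutation 1 replicate (replicates 1 to 3, 0.0648, 0.065 and 0.059) or any mutation 3 replicate (0.0662, 0.0645 and 0.0612) was left out. Of its members 15 rose and 9 fell without wild-type replicate 1.

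Mesenchymal markers had 3 of 27 up and 9 down with mutation 2 (median -0.10, adjusted p = 0.288, 5 and 9 adjusted over the list alone), but 11 up and 11 down with a median of 0.11 without wild-type replicate 1. FN1 fell from 408 ± 149 to 74.1 ± 3.53 CPM, CDH11 (ENSG00000140937, chromosome 16, 64943753 to 65126112) from 237 ± 14 to 117 ± 5.41 and VIM from 1580 ± 514 to 733 ± 10.4, while TNC rose from 65.1 ± 4.82 to 132 ± 3.49. Epithelial markers had 2 of 30 up and 8 down (median -0.17, adjusted p = 0.68, 2 and 7 adjusted over the list alone), and without wild-type replicate 1 they had 15 up and 9 down with a median of 0.31. CDH1 fell to 0.8 ± 0.344 CPM (log2 fold change -2.76, adjusted p = 0.0319), a call that ended without wild-type replicate 1 (-0.61, adjusted p = 0.11). Hypoxia and glycolysis genes had 5 of 32 up and 3 down (median 0.31, adjusted p = 0.263, 4 and 3 adjusted over the list alone), and without wild-type replicate 1 28 were up and 3 down with a median of 0.82 (adjusted p = 2.6e-13). HK2, a glycolytic hexokinase, rose from 44.7 ± 24.8 to 146 ± 3.95 CPM.

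Of the microRNA lists, host transcripts had 2 of 18 up and 4 down with mutation 2 (median -0.37, adjusted p = 0.809) and let-7 targets 7 of 30 up and 5 down (0.20, 0.389). Targets of miR-200 had 8 of 27 up and 10 down (-0.09, 0.641, with adjusted p = 0.0288 and a median of -0.28 without wild-type replicate 1). Targets of miR-21 and miR-17 had 8 of 32 up and 8 down (0.03, mean -0.06, adjusted p = 0.809, 8 and 11 adjusted over the list alone) and miR-29 and miR-221 targets 2 of 35 up and 11 down (-0.19, 0.492). NF-kB cytokines had 10 of 29 up and 6 down (0.28, 0.507, 12 and 7 adjusted over the list alone, and adjusted p = 0.00488 without wild-type replicate 1). IL11 fell from 55.4 ± 2.82 to 7.24 ± 0.566 CPM. Migration genes had 10 of 38 up and 13 down (-0.05, 0.688, 13 and 18 adjusted over the list alone) and mesenchymal lineage genes 1 of 16 up and 7 down (-0.33, 0.492, 2 and 8 adjusted over the list alone). ATF4 and unfolded protein genes had 2 of 31 up and 14 down (-0.33, 0.165) and YAP/TAZ targets 7 of 22 up and 5 down (0.09, mean -0.01, adjusted p = 0.805, 7 and 6 adjusted over the list alone). Luminal and basal markers had 3 of 14 up and 6 down (-0.04, 0.0523, and adjusted p = 0.0216 and 0.0218 without wild-type replicates 2 and 3). Markers of other cell types had 0 of 7 up and 2 down (-0.25, 0.492), mitochondrial mRNAs 0 of 13 called (0.26, 0.288) and nuclear-retained RNAs 0 of 9 up and 2 down (0.14, 0.805). Many of these counts rested on wild-type replicate 1. Without it the counts up and down were 4 and 9 for host transcripts, 12 and 9 for let-7 targets (median 0.07), 13 and 14 for miR-21 and miR-17 targets (median 0.00) and 13 and 15 for miR-29 and miR-221 targets. They were 18 and 9 for NF-kB cytokines, 18 and 19 for migration genes (median -0.11), 4 and 8 for lineage genes, 12 and 18 for ATF4 and unfolded protein genes and 11 and 9 for YAP/TAZ targets. Luminal and basal markers then had 7 and 7 (median 0.01), markers of other cell types 1 and 2 (median -0.10), mitochondrial mRNAs 3 and 3 (median -0.03) and nuclear-retained RNAs 3 and 2 (median -0.03).

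In total 5588 genes were called between mutation 2 and wild type (37%), 2555 higher and 3033 lower, and 1433 were called and at least 2-fold apart. Without wild-type replicate 1 the count was 10726, with 5213 higher and 5513 lower. Libraries did not overlap for 6427 genes (42.6%). Of 33 genes that the rule named by size of change, 17 moved by over 1.5 times without wild-type replicate 1.

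With mutation 3 against wild type, IL24 (ENSG00000162892, chromosome 1, 206897443 to 206904139), a cytokine, rose 16.3-fold from 5.47 ± 3.06 to 88.9 ± 1.65 CPM. PADI1, an enzyme that converts arginine to citrulline, rose 13.6-fold from 2.97 ± 1.3 to 40.2 ± 2.32. GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176), a stress-induced cytokine, rose 13.2-fold from 22.3 ± 15.3 to 293 ± 12.5 CPM (log2 fold change 3.72, and 4.45 without wild-type replicate 1). TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600), an inhibitor of thioredoxin, rose 10.8-fold from 82.2 ± 56.9 to 891 ± 3.3 (3.44, and 4.18 without wild-type replicate 1). SOX4 (ENSG00000124766, chromosome 6, 21592768 to 21598619), a developmental transcription factor, lay at 0.0209 ± 0.0361 against 38.4 ± 8.81 CPM. TRIML2 was at 0 in each mutation 3 library and at least 73.8-fold lower (14.9 ± 9.51 CPM in wild type). SPANXB1, a testis antigen with near-identical copies, was also at 0 and had 0.591, 220 and 227 CPM in wild-type replicates 1, 2 and 3. TXNIP, IL24 and SOX4 also moved with mutation 1, to 1070 to 1110, 46.6 to 48.5 and 2.15 to 3.17 CPM.

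G1/S genes fell with mutation 3 in 36 of 37 members and rose in 0 (median -1.21, adjusted p = 6.75e-25). PCNA fell to 80.9 ± 2.82 CPM, CDC6 to 31.7 ± 0.694 and CLSPN from 56.7 ± 3.79 to 12.4 ± 0.31. G2/M genes fell in 20 of 35 members and rose in 2 (median -0.34, adjusted p = 0.0265, 0.621 with an estimated correlation and 0.0713 without wild-type replicate 1). CDCA3, a mitotic entry factor, fell from 81.5 ± 7.19 to 35.7 ± 1.74 CPM, while ANLN, which organises the contractile ring, was among the 2 that rose. Interferon-stimulated genes fell in 22 of 37 members and rose in 3 (median -0.73, adjusted p = 4.87e-06, 3 and 23 adjusted over the list alone). IFIT3 fell to 37.9 ± 1.26 CPM, OASL to 3.34 ± 0.522 and HERC6, a ubiquitin ligase, from 15.8 ± 1.96 to 2.24 ± 0.21, while STAT2 and IFITM1 were among the 3 that rose. Of the list tests that passed against wild type (8, 4 and 6 for mutations 1, 2 and 3, of 72), 3 held with an estimated correlation: G1/S genes with mutation 1 (adjusted p = 0.000152) and mutation 3 (9.02e-05), and interferon-stimulated genes with mutation 3 (0.0043). G2/M genes had 7 up and 22 down (median -0.22) without wild-type replicate 1, and interferon-stimulated genes 9 up and 24 down.

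**Figure D2:**
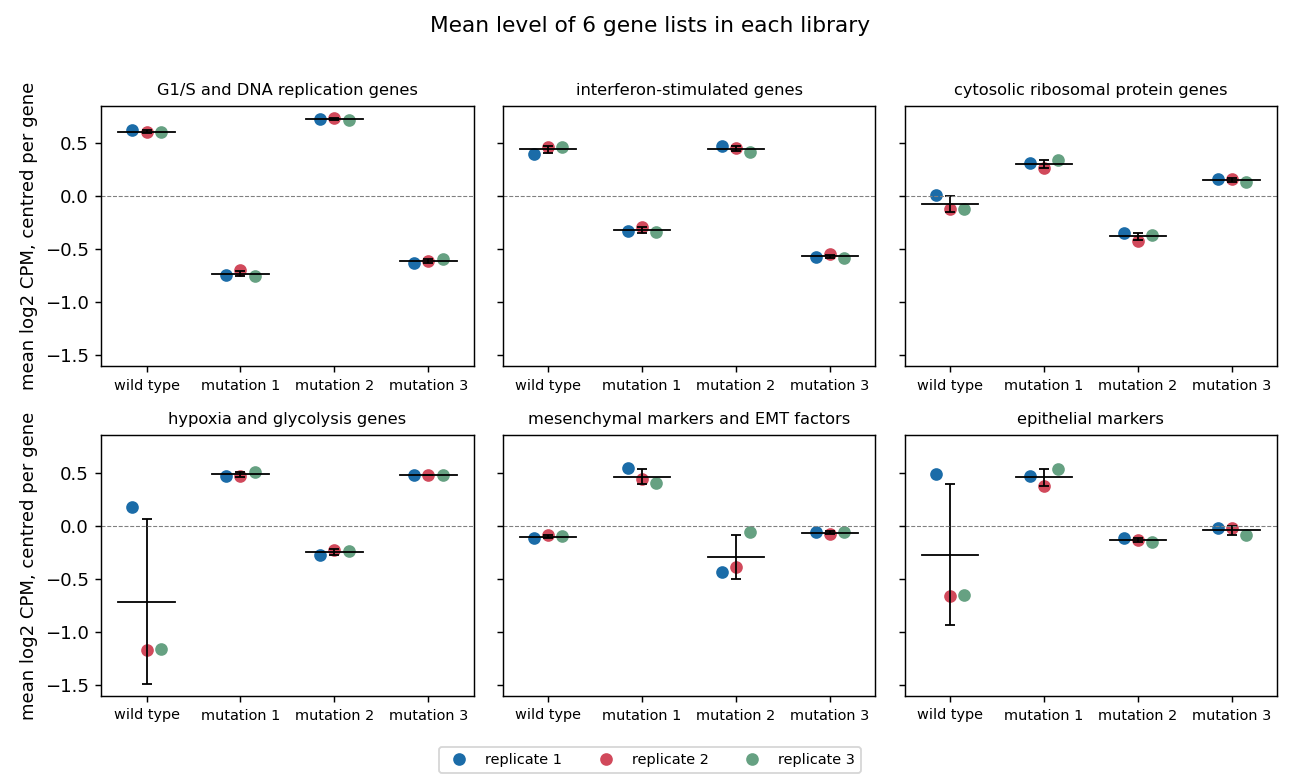
Mean log2 CPM of 6 gene lists in each library, centred on each gene's mean over all libraries, with a point per library coloured by replicate, a bar at the group mean and the SD of 3 libraries. G1/S genes lie between 0.6 and 0.74 in wild type and mutation 2 and between -0.75 and -0.59 in mutations 1 and 3, and in the hypoxia list wild-type replicate 1 lies at 0.18 against -1.17 and -1.16 in the other wild-type libraries.

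Mesenchymal markers had 8 of 27 up and 6 down with mutation 3 (median 0.00, mean -0.09, adjusted p = 0.918). CDH11 fell from 237 ± 14 to 68.3 ± 2.4 CPM and FN1 from 408 ± 149 to 198 ± 4.42. ACTA2, the smooth muscle actin, rose from 1.4 ± 0.0426 to 5.07 ± 0.875. VIM lay at 1200 ± 7.31 against 1580 ± 514 (adjusted p = 0.0902, and past the threshold without wild-type replicate 1 with a log2 fold change of -0.64). Epithelial markers had 7 of 30 up and 8 down (median 0.05, mean -0.07, adjusted p = 0.933, 7 and 7 adjusted over the list alone). CLDN1 fell from 8.79 ± 1.59 to 1.45 ± 0.428 CPM and CDH1 to 0.601 ± 0.0832 (log2 fold change -3.14, adjusted p = 0.0132, and -0.98 with adjusted p = 0.0125 without wild-type replicate 1). The microRNA machinery had 9 of 26 up and 8 down (median 0.04, adjusted p = 0.72, 9 and 9 adjusted over the list alone). DGCR8 fell to 20 ± 0.653 CPM (log2 fold change -1.40, SE 0.17, adjusted p = 4.89e-05). RAN, the GTPase of nuclear export, fell from 549 ± 88.5 to 249 ± 4.47, and AGO4 rose from 10.6 ± 2.01 to 25.4 ± 1.65. When wild-type replicate 1 was left out the counts up and down were 13 and 10 for mesenchymal markers, 14 and 9 for epithelial markers and 10 and 12 for the machinery, whose median was then -0.03.

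Hypoxia and glycolysis genes rose with mutation 3 in 21 of 32 members and fell in 1 (median 0.72, adjusted p = 0.000262, and 0.621 with an estimated correlation). VEGFA rose to 1140 ± 10.8 CPM and SLC2A3, a glucose transporter, from 38 ± 7.82 to 193 ± 4.25, while ANGPTL4 fell to 7.24 ± 0.1. The median was 1.23 without wild-type replicate 1. Nuclear-retained RNAs rose in 4 of 9 members and fell in 0 (median 0.49, adjusted p = 0.00435, 0.621 with an estimated correlation, and a median of 0.24 without wild-type replicate 1). KCNQ1OT1 rose to 21.1 ± 2.13 CPM and MALAT1 to 3140 ± 37.1. Ribosomal protein genes rose in 45 of 71 members and fell in 3 (median 0.21, adjusted p = 0.0112, and 0.621 with an estimated correlation). RPS12 rose from 618 ± 5.2 to 966 ± 7.5 CPM, and RPS10 and RPS29 were among the 3 that fell. Nuclear-retained RNAs had 6 up and 1 down without wild-type replicate 1, and ribosomal protein genes 58 up and 7 down.

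**Figure D3:**
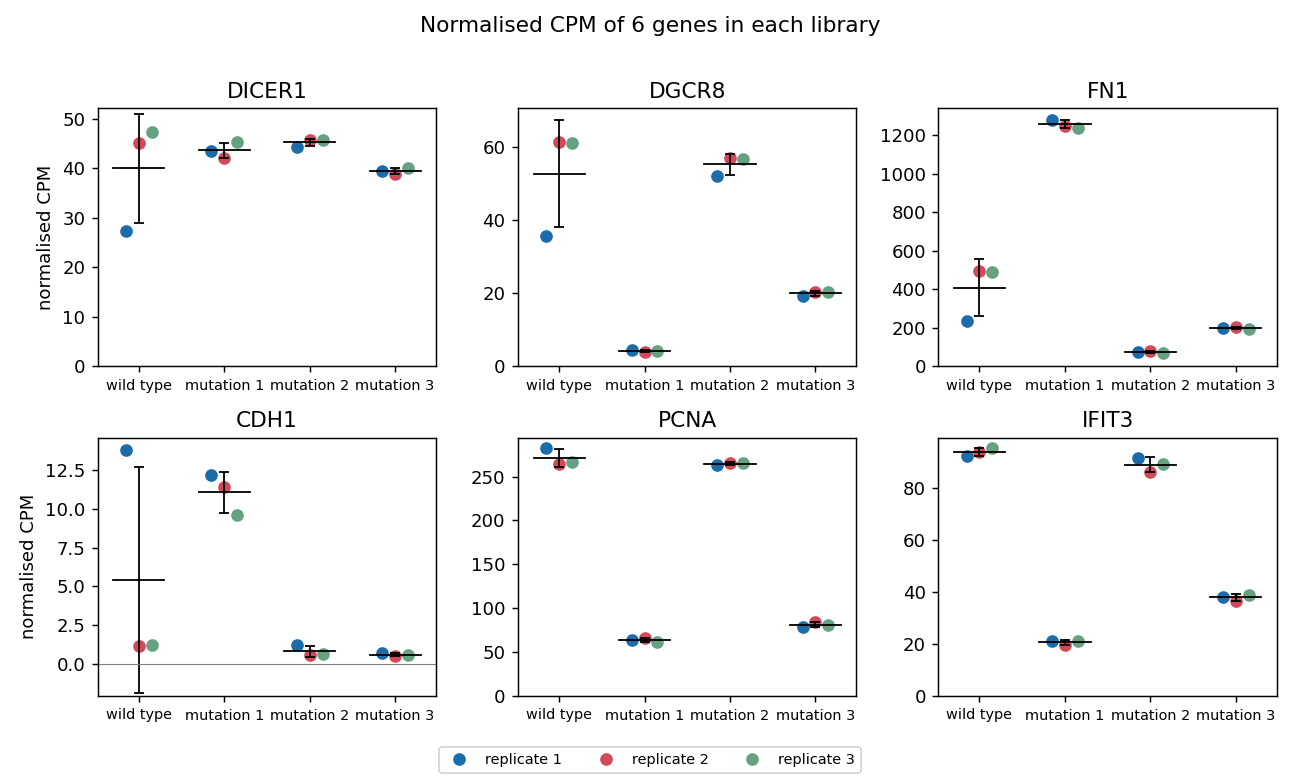
Normalised level (CPM) of DICER1, DGCR8, FN1, CDH1, PCNA and IFIT3 in each library by group, with a point per library, a bar at the mean and the SD of 3 libraries. DGCR8 lies at 4.19 ± 0.32 with mutation 1 and 20 ± 0.653 with mutation 3, and CDH1 in wild type at 13.8 in replicate 1 and 1.17 and 1.23 in the other replicates.

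The other lists did not pass with mutation 3. Host transcripts had 7 of 18 up and 5 down (median 0.47, adjusted p = 0.622), let-7 targets 12 of 30 up and 10 down (0.02, mean -0.06, adjusted p = 0.607) and miR-200 targets 7 of 27 up and 8 down (0.07, mean -0.07, adjusted p = 0.629). Targets of miR-21 and miR-17 had 11 of 32 up and 11 down (-0.04, mean 0.11, adjusted p = 0.629) and miR-29 and miR-221 targets 10 of 35 up and 7 down (0.14, mean -0.01, adjusted p = 0.622). NF-kB cytokines had 10 of 29 up and 14 down (-0.37, 0.629), and 14 up and 14 down with a median of 0.28 without wild-type replicate 1. IL1B rose from 18.6 ± 7 to 125 ± 2.88 CPM and IL11 fell to 9.95 ± 0.433. Mesenchymal lineage genes had 6 of 16 up and 3 down (0.25, 0.282) and ATF4 and unfolded protein genes 10 of 31 up and 16 down (-0.19, 0.361). Cholesterol genes had 4 of 25 up and 9 down (-0.03, 0.477), YAP/TAZ targets 9 of 22 up and 6 down (0.28, 0.622) and migration genes 13 of 38 up and 10 down (0.07, mean -0.21, adjusted p = 0.691). Luminal and basal markers had 3 of 14 up and 6 down (-0.26, 0.526) and markers of other cell types 0 of 7 up and 3 down (-0.48, 0.622). Mitochondrial mRNAs had 3 of 13 up and 1 down (0.32, 0.629, 1 and 1 adjusted over the list alone) and histone genes 1 of 12 up and 4 down (-0.69, 0.622, 1 and 2 adjusted over the list alone). With wild-type replicate 1 left out the counts up and down were 9 and 8 for host transcripts (median 0.23), 14 and 15 for let-7 targets (0.04), 12 and 11 for miR-200 targets, 18 and 10 for miR-29 and miR-221 targets (0.26), 8 and 6 for lineage genes and 7 and 14 for cholesterol genes (-0.19). Mitochondrial mRNAs then had 5 and 5 (median -0.12), luminal and basal markers 6 and 7 (median 0.13), markers of other cell types 1 and 3 (median -0.09), histone genes 2 and 6 and YAP/TAZ targets 12 and 8 (median 0.18). The medians of miR-21 and miR-17 targets (0.08) and migration genes (-0.02) also turned sign.

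In total 8948 genes were called between mutation 3 and wild type (59.3%), 4235 higher and 4713 lower, and 3630 were called and at least 2-fold apart. Libraries did not overlap for 9214 genes (61%). Of 35 genes that the rule named by size of change, 12 moved by over 1.5 times without wild-type replicate 1, and the F test called 12522 genes among the 4 groups (83%).

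Of the genes called the same way in all 3 mutations, MUC5AC had means of 0.0224, 0.248 and 0.217 CPM in mutations 1, 2 and 3, against 8.47, 1010 and 1000 CPM in wild-type replicates 1, 2 and 3. AGR2 was at 0 with mutations 2 and 3 and at least 94.5-fold and 89.7-fold lower there. SPDEF (ENSG00000124664, chromosome 6, 34537802 to 34556333), a transcription factor, lay at 0.435 ± 0.0395, 0.0469 ± 0.0813 and 0.27 ± 0.073 CPM, FOXA2 at 0.83 ± 0.284, 0.181 ± 0.157 and 0.0741 ± 0.128, and MUC5B at 0.161 ± 0.145, 0.107 ± 0.0761 and 0.432 ± 0.251. FAM184A rose from 1.27 ± 0.545 CPM by 4.77-fold, 4.21-fold and 6.2-fold. GABRE, a subunit of GABA receptors, rose from 5.13 ± 6.08 to 22.2 ± 0.711, 37.9 ± 1.19 and 45 ± 1.83 CPM. Its log2 fold changes were 2.13, 2.90 and 3.15, and 3.77, 4.55 and 4.79 without wild-type replicate 1. SH3D21 rose from 7.98 ± 2.23 CPM by 9.11-fold, 3.88-fold and 7.17-fold, and it overlaps EVA1B, so its counts are uncertain without strand.

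The shared calls numbered 1133 up and 1447 down. Independent lists of the same sizes would share 232.8 and 345.7. Simulated unchanged groups against 1 redrawn set of wild-type counts shared 129 and 97.6. The simulated comparisons held a mean of only 318, 327 and 321 calls, so their shared counts cannot be set directly against the real ones. The redrawn wild-type counts also did not keep the split of replicate 1 from replicates 2 and 3. By pairs the shared increases were 1341 for mutations 1 and 2 (829.8 independent, 143 simulated), 3301 for mutations 1 and 3 (1375.4 and 141) and 1426 for mutations 2 and 3 (716.9 and 144). The shared decreases were 1678 (1107.2 and 111), 3808 (1720.5 and 110) and 1801 (947 and 113) in the same order, and opposite calls numbered 1255, 367 and 781. Across genes the covariance of log2 fold changes was 0.5251, 1.298 and 0.5832, against 0.158 in the simulation, and the correlation was 0.4054, 0.7151 and 0.5409, against simulated values of 0.896, 0.893 and 0.899. The wild-type libraries were not split, since a part would hold fewer than 2 libraries, and part of the excess over independent lists may come from the shared wild-type libraries. Without wild-type replicate 1 the shared calls numbered 6336, with 3013 up and 3323 down.

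Between mutations 1 and 2, LPL, which hydrolyses circulating triglycerides, was 220-fold higher with mutation 1 at 20.4 ± 0.833 against 0.0827 ± 0.0262 CPM. SEMA5A, a guidance molecule, was at least 45.6-fold higher. RIOX1 (ENSG00000170468, chromosome 14, 73490964 to 73493392), a histone demethylase, was 42.8-fold lower with mutation 1 at 0.404 ± 0.077 against 17.8 ± 1.79 CPM. PRMT6 (ENSG00000198890, chromosome 1, 107056679 to 107067636), an arginine methyltransferase, was 36.9-fold lower (log2 difference -5.21, SE 0.23). G1/S genes were lower with mutation 1 in 35 of 37 members and higher in 1 (median -1.46, adjusted p = 3.26e-22) and interferon-stimulated genes lower in 20 of 37 and higher in 9 (-0.79, 0.00496). Mesenchymal markers were higher in 17 of 27 and lower in 3 (0.85, 0.00295, 18 and 3 adjusted over the list alone). FN1 lay at 1260 ± 20.9 against 74.1 ± 3.53 CPM and TNC at 418 ± 12.7 against 132 ± 3.49. These 3 tests held with an estimated correlation, at adjusted p = 9.71e-05, 0.044 and 0.044. Epithelial markers also leaned higher with mutation 1, in 10 of 30 and lower in 6 (0.72, 0.337), and without wild-type replicate 1 in 20 and lower in 9 (adjusted p = 0.0133). Ribosomal protein genes were higher with mutation 1 in 67 of 71 members and lower in 0 (0.68, 9.65e-13, and adjusted p = 0.17 with an estimated correlation). Mitochondrial mRNAs were lower in 11 of 13 (-2.28, 0.000385, and adjusted p = 0.393 with an estimated correlation). There were 9879 calls (65.4%), 4800 higher and 5079 lower with mutation 1, 4930 of them at least 2-fold apart. Libraries did not overlap for 12323 genes (81.6%).

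Between mutations 1 and 3, CCL2 (ENSG00000108691, chromosome 17, 34255218 to 34257203), a monocyte chemokine, was at 167 ± 3.32 CPM with mutation 1 and at 0.0456 ± 0.0399 with mutation 3, a ratio of 3730 (counting interval 1030 to 30800). TRIML2 was at least 71.3-fold higher. MT-ND1 was 18.1-fold lower with mutation 1 at 257 ± 12.4 against 4640 ± 185 CPM. Mesenchymal markers were higher with mutation 1 in 13 of 27 members and lower in 3 (median 0.51, adjusted p = 0.000351), TNC at 418 ± 12.7 against 94.2 ± 2.52 CPM. ATF4 and unfolded protein genes were higher in 16 of 31 and lower in 3 (0.42, 0.000489). HSPA5, the main chaperone of the endoplasmic reticulum, lay at 3820 ± 20.1 against 1080 ± 22.3 CPM, and TRIB3, SESN2 and EDEM1 were the members that were lower. Histone genes were higher in 8 of 12 and lower in 1 (1.15, 0.000984, 9 and 1 adjusted over the list alone), among them H2BC5, a core histone gene, at 14.2 ± 0.985 against 5.03 ± 0.52 CPM. These 3 tests held with an estimated correlation, at adjusted p = 0.0219, 0.0219 and 0.0361. Epithelial markers also leaned higher with mutation 1, in 9 of 30 and lower in 1 (0.27, 0.225, 8 and 1 adjusted over the list alone), and without wild-type replicate 1 in 18 and lower in 5 (adjusted p = 0.0198). Without it mesenchymal markers had 16 higher and 6 lower, and ATF4 and unfolded protein genes 22 and 8. G1/S genes had 9 of 37 higher and 14 lower (-0.16, 0.367, 9 and 15 adjusted over the list alone) and interferon-stimulated genes 13 of 37 higher and 6 lower (0.15, 0.368). There were 6454 calls (42.8%), 3053 higher and 3401 lower with mutation 1, 2111 of them at least 2-fold apart. Without wild-type replicate 1, which enters only the spread estimate here, there were 10521 calls. For 10536 genes libraries did not overlap (69.8%).

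Between mutations 2 and 3, GYPC, a red cell membrane protein, was at 25.5 ± 1.33 CPM with mutation 2 and at least 126-fold higher than with mutation 3, where it was at 0. PTPRN2 was at least 89.7-fold higher with mutation 2. BAHCC1 was 35.5-fold lower with mutation 2 at 1.14 ± 0.2 against 40.8 ± 0.349 CPM, and GDF15 21.9-fold lower at 13.4 ± 0.193 against 293 ± 12.5. G1/S genes were higher with mutation 2 in 36 of 37 members and lower in 1 (median 1.27, adjusted p = 1.72e-35), and interferon-stimulated genes in 25 of 37 and lower in 4 (0.71, 6.21e-07, 26 and 4 adjusted over the list alone). Both held with an estimated correlation, at adjusted p = 3.75e-05 and 0.0029. Ribosomal protein genes were lower in 66 of 71 members and higher in 1 (-0.56, 9.95e-14, and adjusted p = 0.303 with an estimated correlation). G2/M genes were higher in 26 of 35 and lower in 2 (0.41, 0.000651, and adjusted p = 0.315 with an estimated correlation). Mesenchymal markers had 5 of 27 higher and 11 lower (-0.39, 0.441, 5 and 13 adjusted over the list alone, and 6 and 17 with adjusted p = 0.00965 without wild-type replicate 1). There were 7980 calls (52.9%), 4107 higher and 3873 lower with mutation 2, 2838 of them at least 2-fold apart. Libraries did not overlap for 11454 genes (75.9%).

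Genes with seed matches of microRNA families were compared by strand. Dicer releases the 5p and 3p strands of each precursor, and a difference in their silencing would move genes with 5p and 3p sites apart. The mean t value of 15 families from the 5p strand minus that of 15 families from the 3p strand was -0.42 with mutation 1 (permutation p = 0.267), 0.36 with mutation 2 (p = 0.358 by permutation) and -0.33 with mutation 3 (p = 0.473 by permutation), and 0.473 for each after adjustment over the 3 comparisons. The means were 0.62 and 1.04 for 5p and 3p with mutation 1, 1.2 and 0.84 with mutation 2, and 0.98 and 1.31 with mutation 3. With 8-base sites only, the differences were -0.69 (permutation p = 0.0814), -0.05 (permutation p = 0.914) and -0.90 (permutation p = 0.0448) for mutations 1, 2 and 3, not adjusted over the comparisons. With the 5 CPM filter they were -0.75 (permutation p = 0.0632), 0.28 (permutation p = 0.517) and -0.52 (permutation p = 0.255).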

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

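The tests of a mutation 2 library under a wild-type label and of chromosome dosage in wild-type replicate 1 were chosen after the library correlations had been seen. Each list below differed between mutant groups in a direct test, with the preset and with the estimated correlation between genes.

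Mesenchymal markers lay higher with mutation 1 than with mutation 2 (median log2 difference 0.85, adjusted p = 0.00295) and mutation 3 (0.51, adjusted p = 0.000351), FN1 at 1260 ± 20.9 CPM against 74.1 ± 3.53 and 198 ± 4.42. Epithelial markers leaned the same way (0.72, adjusted p = 0.337, and 0.27, adjusted p = 0.225) and passed without wild-type replicate 1 (adjusted p = 0.0133 and 0.0198), so the difference was not shown to be particular to mesenchymal genes. Interferon-stimulated genes lay lower with mutation 1 than with mutation 2 (-0.79, adjusted p = 0.00496) and higher with mutation 2 than with mutation 3 (0.71, adjusted p = 6.21e-07), IFIT3 at 20.6 ± 1, 89.1 ± 2.79 and 37.9 ± 1.26 CPM with mutations 1, 2 and 3. G1/S genes lay lower with mutation 1 than with mutation 2 (-1.46, adjusted p = 3.26e-22) and higher with mutation 2 than with mutation 3 (1.27, adjusted p = 1.72e-35), PCNA at 63.9 ± 2.15, 265 ± 1.85 and 80.9 ± 2.82 CPM. ATF4 and unfolded protein genes (0.42, adjusted p = 0.000489) and histone genes (1.15, adjusted p = 0.000984) lay higher with mutation 1 than with mutation 3. Chromosome dosage was not tested as a cause of these differences between mutations.

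Wild-type replicate 1 differed from wild-type replicates 2 and 3, for example in MUC5AC (8.47 against 1010 and 1000 CPM) and CDH1 (13.8 against 1.17 and 1.23), and wild-type replicates 2 and 3 lay further from all 9 mutant libraries (Spearman correlation 0.852 to 0.933) than replicate 1 did (0.912 to 0.97). A further library of the same mutation 2 culture under a wild-type label was argued against. Replicate 1 correlated at up to 0.97 with the mutation 2 libraries, which correlated at 0.998 with each other. AGR2 was at 0 in each mutation 2 library and at 11 CPM in replicate 1. A mutation 2 library from another culture need not come nearer, so such a swap stayed open. A trend with GC content and transcript length was argued against as the whole cause, since 90% of the 2108 genes over 2-fold apart stayed so after the trend was removed. Cells with a different chromosome dosage could account for part of the difference: medians over 20-Mb bins spread 3.07 and 3.11 times as widely as shuffled positions, against 0.972 between wild-type replicates 2 and 3, and 74.9% of 2093 genes stayed over 2-fold apart after the bin medians were subtracted. Set against the mutant libraries, wild-type replicates 2 and 3 thus departed more than replicate 1. The bin ratio against a mutation 2 library was likewise 3.68 for wild-type replicate 2 and 1.95 for replicate 1. DICER1 went the other way, with its lowest level in wild-type replicate 1 (27.4 CPM). Which wild-type libraries reflect the intended wild-type condition stayed open. Other cells of the line, a treatment difference and a biological difference between wild-type cultures were not tested.

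Many genes were called between each mutation and wild type, and the groups may differ in more than the plasmid. After bin medians were subtracted, 88.2%, 77.7% and 84.8% of called genes over 2-fold apart with mutations 1, 2 and 3 stayed so. The SD of the bin medians was only 0.308, 0.268 and 0.279 in log2, so most such genes would stay so in any case. These shares show only that shifts shared by whole bins were small next to 2-fold. Dosage changes within a bin and effects of dosage on genes elsewhere were not tested, so dosage stayed open as a cause. With a variance for each group, 76%, 55.9% and 70% of calls were kept. That fit weights each group by a factor shared by all genes, and does not give each gene its own wild-type spread. It therefore cannot decide whether the wild-type spread was understated, which stayed open. The fit with only the 2 groups kept 82.8%, 47.5% and 76.5%, so much of the count for mutation 2 may rest on the shared spread estimate. For each pair of groups 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05: the real count and the highest other were 10412 and 0, 5588 and 2, and 8948 and 0 against wild type, and 9879 and 0, 6454 and 0, and 7980 and 0 between mutations 1 and 2, 1 and 3, and 2 and 3. The number of genes differing among the 4 groups (12522, highest other 6094) was reached in 1 of 100 regroupings, the real one. The same held for the number shared by the mutations (2580, highest other 1701). Libraries of a group, apart from wild-type replicate 1, were nearly alike and may not be separate cultures. Regrouping them therefore cannot exclude chance differences between cultures, or shared calls that come from the common wild-type libraries. Effects of the mutant Dicer proteins, differences between transfected cultures and differences in the amount of plasmid stayed open and untested.

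Single-exon protein-coding genes were lower as a class with mutations 1 and 3, RIOX1 at 0.404 ± 0.077 CPM with mutation 1 and 17.8 ± 1.79 with mutation 2. The median log2 fold change of 186 such genes was -1.23 with mutation 1, where 10000 sets of multi-exon genes matched in level gave -0.31 to 0.11, and -0.43 with mutation 3 (matched sets -0.26 to 0.05), against -0.06 with mutation 2 (matched sets -0.14 to 0.05), so that no shift of the class was seen there. A trend with GC content and transcript length was argued against, since the medians after its removal were -1.12 and -0.40 for mutations 1 and 3 (0.00 for mutation 2, where there was no shift to explain). The class was examined because PRMT6 and RIOX1, which lack introns, stood among the top genes, and the histone genes of the list were left out when the test was written. That list leaned the other way with mutation 1 (median 0.61, 4 of 12 up and 1 down) and not with mutation 3 (-0.69, 1 up and 4 down). The shift with mutation 1 is thus that of the class without histone genes. A change in RNA decay or export, in growth rate or in library preparation between cultures could produce such a shift and was not tested.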

How the results depend on the processing

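The variance per group and the no-overlap rule were chosen after the data had been examined. With RLE scaling, DESeq2, limma-voom, no filter, a 5 CPM filter or DICER1 removed before scaling, the counts of called genes stayed within 1.5 times, and 77.5 to 100% of calls were kept, 0 in the opposite direction. Of 773 gene results for named genes, 0 reversed: 4468 comparisons with alternatives other than leaving out a library kept their side of the threshold and 94 lost their call, and for leave-one-out 9015 kept it and 261 lost it. The rule took these results because they were called in the main fit, many with the largest folds. Their stability was thus largely set in advance and says little about how firm calls are in general. Of the 144 list tests, 465 comparisons kept their side, 65 gained a call, 43 lost it and 3 turned direction, and for leave-one-out these numbers were 1657, 16, 35 and 20.

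Requiring at least 2-fold left 5302, 1433 and 3630 genes for mutations 1, 2 and 3 against wild type, 4930, 2111 and 2838 for mutations 1 and 2, 1 and 3, and 2 and 3, 7406 genes differing among the 4 groups and 596 genes changed the same way in all 3 mutations, which follows from the added limit. With only the 2 groups in the fit, mutation 2 against wild type had 2589 genes, mutation 1 against mutation 3 had 10073 and 1148 were shared; with a variance per group these were 3481, 10110 and 1620, and the cause was not tested. Of 18 lists past the threshold against wild type, camera left 3 with an estimated correlation, and fry, which asks another question, called 51.

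Leaving out a library gave 9644 to 13064 genes for mutation 1 against wild type, 4208 to 10726 for mutation 2, 7969 to 12179 for mutation 3, 8963 to 12677 for mutations 1 and 2, 5146 to 10521 for mutations 1 and 3, 6763 to 11518 for mutations 2 and 3, 12013 to 15006 genes differing among the 4 groups, 1866 to 6336 genes changed the same way in all 3 mutations and 17 to 21 lists, each highest count of genes between 2 groups or shared without wild-type replicate 1. DICER1 ranged from -0.08 to 0.26 with mutation 1, -0.02 to 0.31 with mutation 2 and -0.23 to 0.11 with mutation 3, the lowest without wild-type replicate 1, and in mutation 3 it was 0.01 with limma-voom (adjusted p = 0.943) and 0.01 with a variance per group (adjusted p = 0.962); the cause was not tested.

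Lists that turned direction did so past no threshold. With the 5 CPM filter the adjusted p was 0.799 for the list markers of other cell types, mutation 2 vs wild type, and 0.83 for epithelial markers with mutation 3, and with fry 0.835 for microRNA machinery between mutations 1 and 3. Leave-one-out adjusted p ranged for mutation 1 from 0.641 to 0.846 (machinery) and 0.681 to 0.846 (luminal and basal), for mutation 2 from 0.16 to 0.739 (epithelial), 0.286 to 0.942 (miR-29 and miR-221 targets), 0.814 to 0.983 (interferon) and 0.395 to 0.814 (nuclear RNAs), for mutation 3 from 0.0635 to 0.997 (epithelial), 0.268 to 0.956 (lineage), 0.627 to 0.808 (machinery), 0.451 to 0.858 (miR-200 targets) and 0.451 to 0.707 (NF-kB), and 0.822 to 0.988 for machinery between mutations 1 and 3 and 0.756 to 0.978 for mitochondrial mRNAs between mutations 2 and 3. In the seed test, 8-base sites gave -0.05 with mutation 2 and -0.90 with mutation 3, against 0.36 and -0.33 with all sites, and the cause was not tested.

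No paired analysis was possible because the mutant samples carry no replicate number in their labels. Genes with few counts, such as AGR2 with mutations 2 and 3, had only lower bounds on their folds at these depths.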

Other observations

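The single-exon and dosage tests on groups are given above; the seed test below was planned before the data were examined. Single members of lists that did not pass also moved. BMP4 (ENSG00000125378, chromosome 14, 53949736 to 53958761), a secreted morphogen, fell from 321 ± 18.7 CPM to 40.3 ± 1.2 with mutation 1 and 80.9 ± 2.63 with mutation 3, and lay at 267 ± 4.75 with mutation 2. RUNX2, a transcription factor of bone formation, rose from 37.4 ± 1.09 to 168 ± 2.1 with mutation 1 and 110 ± 4.66 with mutation 3. CEBPB, a factor of adipocyte and stress programmes, rose from 103 ± 4.45 to 529 ± 13 with mutation 1 and 169 ± 6.65 with mutation 3, and fell to 78.4 ± 2.18 with mutation 2. MYC, a growth regulator, rose from 127 ± 2.79 to 396 ± 13.7, 204 ± 2.67 and 238 ± 5.12 with mutations 1, 2 and 3.

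Between mutations further lists passed with the preset correlation and not with the estimated one. MicroRNA host transcripts were lower with mutation 1 than with mutation 3 in 10 of 18 members and higher in 0 (median -1.39, or -0.88 with a bound for the member at 0, adjusted p = 0.00327, and adjusted p = 0.0752 with an estimated correlation), MIR3142HG 54.4-fold lower at 0.319 ± 0.141 against 17.5 ± 0.938 CPM (3 higher and 11 lower without wild-type replicate 1). Targets of miR-29 and miR-221 were higher with mutation 1 than with mutation 2 in 21 of 35 members and lower in 6 (0.77, 0.0122, 24 and 7 adjusted over the list alone, and adjusted p = 0.0567 with an estimated correlation). They were also higher with mutation 1 than with mutation 3, in 18 members and lower in 4 (0.41, 0.0194, 18 and 5 adjusted over the list alone, 22 and 8 without wild-type replicate 1, and adjusted p = 0.0752 with an estimated correlation). Mitochondrial mRNAs were lower with mutation 1 than with mutation 3 in 11 of 13 members (-2.36, 1.99e-09, and adjusted p = 0.168 with an estimated correlation).

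Further lists of this kind were higher with mutation 1 than with mutation 2: migration genes (22 of 38 higher and 5 lower, median 0.55, adjusted p = 0.0122, 0.225 with an estimated correlation), cholesterol genes (15 of 25 and 5, 0.63, 0.0226, 0.226), hypoxia genes (14 of 32 and 3, 0.40, 0.012, 0.591), nuclear-retained RNAs (6 of 9 and 0, 0.82, 0.00303, 0.273) and histone genes (7 of 12 and 1, 1.60, 0.00527, 0.0567). ADM lay at 369 ± 5.45 CPM with mutation 1 and 23.3 ± 0.0857 with mutation 2, and RHOB at 128 ± 3.95 and 23.6 ± 1.48. Higher with mutation 1 than with mutation 3 were migration genes (14 of 38 and 5, 0.25, 0.00327, 0.168, 15 and 5 adjusted over the list alone), cholesterol genes (10 of 25 and 1, 0.36, 0.00142, 0.129), G2/M genes (13 of 35 and 2, 0.13, 0.0184, 0.328) and ribosomal protein genes (25 of 71 and 3, 0.16, 0.0184, 0.531). Lower with mutation 2 than with mutation 3 were hypoxia genes (12 of 32 and 1 higher, -0.45, 0.00385, 0.748) and nuclear-retained RNAs (5 of 9 and 0 higher, -0.35, 0.00262, 0.493). The counts higher and lower without wild-type replicate 1 were 24 and 12 (migration) and 21 and 8 (hypoxia) for mutations 1 and 2, 22 and 10 (migration), 17 and 1 (cholesterol), 21 and 8 (G2/M) and 54 and 3 (ribosomal) for mutations 1 and 3, and 5 and 26 (hypoxia) for mutations 2 and 3.

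Other calls between mutations ended when single libraries were left out. The list miR-21-5p and miR-17/20-5p targets, mutation 1 vs mutation 2 (17 of 32 higher and 7 lower, median 0.54, adjusted p = 0.0495, 0.133 with an estimated correlation) had adjusted p = 0.0521 without wild-type replicate 2, 0.0521 without mutation 1 replicate 2, 0.066, 0.0569 and 0.0597 without mutation 2 replicates 1, 2 and 3, and 0.052 without mutation 3 replicate 3. The list miR-21-5p and miR-17/20-5p targets, mutation 1 vs mutation 3 (13 of 32 and 5, 0.20, 0.0322, 0.0942) had 0.0636 without mutation 1 replicate 2, 0.0563, 0.0549 and 0.0546 without mutation 2 replicates 1, 2 and 3, and 0.0609 without mutation 3 replicate 1. The list NF-kB responsive cytokines and regulators, mutation 1 vs mutation 3 (12 of 29 and 5, 0.37, or 0.41 with a bound for the member at 0, adjusted p = 0.0383, 0.328 with an estimated correlation) had 0.0609 and 0.0525 without mutation 3 replicates 1 and 2, and 18 higher and 7 lower without wild-type replicate 1. The list mesenchymal lineage differentiation genes, mutation 2 vs mutation 3 (2 of 16 higher and 7 lower, -0.99, 0.0361, 0.203) had 0.269 with 5 higher and 10 lower without wild-type replicate 1, and lost its call without each mutant library (0.0558 to 0.0863).

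Chromosome medians of log2 CPM in wild-type replicate 1 minus wild-type replicates 2 and 3 were -0.58 for chromosome 13, -0.46 for 14, -0.39 for 12, -0.32 for 16, 0.35 for 2 and 0.63 for 18. The medians of log2 fold changes with mutations 1, 2 and 3 against wild type were -0.64, -0.45 and -0.59 for chromosome 13, -0.47, -0.49 and -0.55 for chromosome 14, and 0.34, 0.40 and 0.38 for chromosome 18. Bin medians spread 1.82, 3.43 and 2.21 times as widely as shuffled positions in these comparisons. Between mutations 1 and 2, 1 and 3, and 2 and 3 they spread 1.48, 1.9 and 1.76 times as widely, so dosage may also enter the comparisons between mutations. Single-exon genes, centred per gene over all libraries, lay at 0.35 to 0.43 in the wild-type libraries, -0.58 to -0.5 with mutation 1, 0.31 to 0.36 with mutation 2 and 0.04 to 0.06 with mutation 3.

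Weaker silencing by microRNAs of the 5p strand would be expected to raise genes with 5p sites over genes with 3p sites. The mean t difference was -0.42, 0.36 and -0.33 with mutations 1, 2 and 3, so that no separation passed with 7-base sites. With 8-base sites mutation 3 gave -0.90 (permutation p = 0.0448, not adjusted over the comparisons), which is the direction opposite to weaker 5p silencing, and mutations 1 and 2 gave -0.69 (permutation p = 0.0814) and -0.05 (permutation p = 0.914). The explanation stayed open. Single families over percentile 97 among 500 other 7-mers, a mark chosen after the values were seen, were miR-29 with mutation 1 (t = 3.49, percentile 99.4), let-7 (t = 2.43, 97.8) and the family of miR-103 and miR-107 (t = 2.6, 97.6) with mutation 2, and miR-181 (t = 3.84, 99.4) and miR-23 (t = 3.19, 97.6) with mutation 3, with no adjustment over the families. With 8-base sites and with the 5 CPM filter the percentiles were 67.8 and 95.6 for miR-29, 97.2 and 86 for let-7, 97 and 73.4 for miR-103 and miR-107, 99 and 99.6 for miR-181, and 99.4 and 99 for miR-23. Other families were over that mark with 8-base sites or the 5 CPM filter, such as miR-15/16 with mutation 2 (100 and 98.8) and miR-25/92 with mutation 3 (99 and 99.8). The mark covers only the upper end. At the lower end the family of miR-221 and miR-222 with mutation 2 had t = -1.99 (percentile 2.6), with percentiles of 17.2 with 8-base sites and 2.0 with the 5 CPM filter. MicroRNA levels were not analysed here.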
